A study of Mus musculus with 4 samples.

How the data were processed

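Polyadenylated RNA from adenomas of ApcMin mice aged 110 days was sequenced as paired-end reads on a BGISEQ-500, with 2 libraries labelled Strap WT and 2 labelled Strap KO. The submitters' processing notes name Bowtie2 2.2.5, RSEM 1.2.12 and the mouse genome build mm10, without giving the role or order of the steps. Per the file headers, each deposited table gives RSEM expected counts per gene. Per the file headers, the same deposited tables give FPKM, a level scaled by transcript length and library size. The tables list genes with an FPKM of at least 0.01, so a gene absent from a table is called not listed, and no upper limit is given for it. Strandedness is not given in the sources used here, so overlapping genes on opposite strands cannot be separated. RSEM shares reads among similar genes, so expected counts of gene families such as the Defa, Oas1, H2 and Akr1c genes are estimates.

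The 4 tables were joined on Entrez gene identifiers with pandas 2.3.3, which gave 17762 genes listed in at least 1 library and 13725 listed in all 4. A total of 17721 identifiers were found in the RefSeq annotation of mm10 (GRCm38.p6), from which coordinates were taken. Gene symbols turned into dates, 25 in all, were restored by identifier. In each library 1 row without a gene was left out, with at most 0.000233% of the counts. Expected counts were rounded to whole numbers. Total expected counts lay between 14084831 and 15640941 per library.

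KO was compared with WT in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test, with genotype as the only term, TMM scaling and the filterByExpr filter, which left 12769 genes. TMM factors were 1.013 and 1.011 in WT and 0.937 and 1.043 in KO. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 32.5%, with 2 residual and 3.9 prior degrees of freedom. The labels do not say that the libraries come from separate animals, nor that libraries of the same number share a litter or day, so p values measure the spread between these libraries alone. Against counting noise alone, replicates differed by a chi-square per degree of freedom of 124 in WT and 62.2 in KO for genes with at least 10 counts.

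A collection of 32 gene lists from textbook knowledge was fixed with the test, the alternatives and the rule for named genes before the data were examined, and 622 of its 668 memberships matched a gene. Lists with at least 5 tested members, 26 in all, were tested with camera from limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Of the 26 lists 10 passed. With an estimated correlation 0 passed, and 0 passed with fry. camera compares a list with the other genes, while fry tests whether its genes move, on balance, one way. For each list the members called over all genes and adjusted over the list alone were counted. The lists were Wnt targets, stem cells, Notch, TGF-beta, polycomb repressive complex 2, SMN complex, cell cycle, MYC and ribosome biogenesis, p53, interferon, hypoxia, immediate early genes and regenerative epithelium. The other lists covered absorptive, goblet, Paneth, enteroendocrine and tuft cells, small intestine and colon regions, fibroblasts, smooth muscle, endothelium, T and natural killer cells, B cells, macrophages, neutrophils, mast cells, enteric neurons, adipocytes, pancreatic acinar cells and sex-linked genes. Another 2 lists, of MHC class I and class II genes with 17 symbols, were chosen after the values were seen.

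Strap, Apc and 12 genes of Wnt, Notch, stem cell and polycomb biology were always named. In each direction up to 10 genes past the threshold with the largest change were to be named, with a mean FPKM of at least 1 and both KO libraries on the same side of both WT libraries. Where under 5 passed, the 5 with the smallest p were named and said not to pass. The 4 members with the smallest p of each list described, all 5 sex-linked genes and members behind small counts were also named, except 1 gene that is not reported here. Genes named beyond this rule are said to have been chosen after their values were seen.

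The alternatives were DESeq2 size factors in the edgeR fit, library size alone, no filter, at least 50 counts in at least 2 libraries, DESeq2 1.42.0, limma with trend on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, each library left out in turn, and a change of at least 2-fold. Leaving out a library leaves 1 sample in a group, which is then assumed to vary like the other group. A crossed pairing of the replicate numbers was added after seeing the data. The median log2 fold change of all genes lay between -0.03 and 0.04 in every setting.

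The test was also run on simulated data with the same design. Of genes changed 2-fold 6 of 48 were called, of those changed 4-fold 35 of 47, of those changed 16-fold 46 of 50, and of those changed 64-fold 48 of 48. There were 7 false calls among 12545 genes, and 0 calls among 12547 genes when none was changed. Of 254 unchanged gene sets 5 were called, and of 3 shifted sets 3 were. Genes were simulated independently of each other. These set rates therefore do not carry over to lists whose members move together, such as the interferon list, with an estimated correlation of 0.322. The simulated libraries also lacked shifts shared by many genes, such as those between the WT libraries. The shares of genes called therefore need not hold for these data, where Usp18, with a 34.5-fold difference, had an edgeR adjusted p of 0.082. Figures were drawn with matplotlib 3.10.9.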

Results

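Polyadenylated RNA was sequenced from adenomas of ApcMin mice, which carry a mutant copy of the tumour suppressor gene Apc and form intestinal tumours. The labels give the tissue as colon adenoma, the strain as C57BL/6 and the age as 110 days. There were 4 libraries, 2 from mice with wild-type Strap (WT) and 2 from mice labelled Strap knockout (KO). Total expected counts were 15422957 and 15255237 in WT replicates 1 and 2, and 15640941 and 14084831 in KO replicates 1 and 2. Between 15270 and 16227 genes were listed per library, and the 20 most abundant genes took between 7.9% and 10.5% of the counts. Levels are given as CPM, the counts scaled to a common total per library with TMM factors, with n = 2 libraries per group. Each ± is an SD between libraries.

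The libraries differed in more than genotype. Across the tested genes the correlation of log2 CPM was 0.934 between the WT libraries and 0.961 between the KO libraries. It was 0.936 and 0.933 between WT replicate 2 and KO replicates 1 and 2, and 0.903 and 0.911 between WT replicate 1 and the same KO libraries. These correlations are across genes, which are not independent replicates. Xist, the transcript that silences an X chromosome in female cells, stood at 968 CPM in WT replicate 1 and 197 CPM in KO replicate 1, against 0.195 and 0.954 CPM in WT and KO replicate 2. The Y-linked genes had the opposite distribution. Ddx3y was at 39.1 CPM in WT replicate 2 and 33.3 CPM in KO replicate 2, with Eif2s3y at 48.9 and 39 CPM, Kdm5d at 38.2 and 31.4 CPM and Uty at 28.8 and 22.4 CPM in the same libraries. In both replicates 1 Ddx3y, Kdm5d and Uty were not listed and Eif2s3y was at most 0.128 CPM, so each genotype held 1 library of each pattern.

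The comparison asks what differs in adenomas of ApcMin mice when Strap is targeted. The deleted part of the gene and the cells in which it was deleted are not given in the sources used here, so the Strap transcripts left in KO cannot be assigned to a source. Strap encodes a WD-repeat protein known for inhibiting TGF-beta signalling and for its place in the SMN complex, which assembles spliceosomal particles. In mm10, Strap lies on chromosome 6 from 137735082 to 137751930. Its expected counts were 2445 and 1724 in WT replicates 1 and 2, and 300 and 364 in KO replicates 1 and 2. Strap stood at 134 ± 31.8 CPM in WT and 22.6 ± 3.05 CPM in KO, a log2 fold change of -2.57 (SE 0.26), so that 16.9% of the WT level was left. Its adjusted p over all 12769 genes was 0.0943 in edgeR and 8.41e-14 in DESeq2. Apc, on chromosome 18 from 34220297 to 34322190, was at 160 ± 31.4 CPM in WT and 120 ± 33.9 CPM in KO, with a log2 fold change of -0.42 (adjusted p = 0.506).

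Ifi44, an interferon-induced gene on chromosome 3 from 151730922 to 151749910, was the 1 gene that rose in KO past the threshold over all genes. It went from 1.26 ± 0.492 CPM in WT to 78.8 ± 2.69 CPM in KO, a log2 fold change of 5.96 (SE 0.33, adjusted p = 0.0288) and a 62.3-fold difference. The other genes with the smallest p among those higher in KO did not pass. They were Slfn5 (log2 fold change 3.86, adjusted p = 0.082), Usp18, whose product removes ISG15 from proteins (5.11, 0.082), Dhx58, which encodes the RNA sensor LGP2 (3.68, 0.0934), and Phf11d (4.57, 0.0943). On the lower side no gene passed. The 5 with the smallest p were Akr1c14, a steroid dehydrogenase gene (57.8 CPM in WT, 6.72 in KO), Ghr, the growth hormone receptor gene (28 and 1.88), Nbl1, which encodes a BMP antagonist (59.7 and 12.8), Iyd, an iodotyrosine deiodinase gene (10.8 and 0.682), and Strap itself. Their adjusted p values lay between 0.082 and 0.1. edgeR called 1 gene higher and 0 lower, against 904 higher and 1110 lower at an unadjusted p under 0.05. DESeq2 called 235 higher and 432 lower, and limma on FPKM called 0 in either direction. Without WT replicate 1 edgeR called 11 higher and 6 lower, and without WT replicate 2 it called 72 higher and 299 lower. Without KO replicate 1, and without KO replicate 2, it called 0 and 0, so the call of Ifi44 was lost.

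Interferon response genes rose together in KO. All 25 measured members were higher, with a median log2 fold change of 3.14 (quartiles 1.66 and 3.79), and the list passed the set test (camera adjusted p = 3.49e-49, and adjusted p = 0.678 with an estimated correlation). In 23 of the 25 both KO libraries lay above both WT libraries. If the 4 libraries were interchangeable, chance would give that order for 16.7% of single genes, and members that move together are not independent. No share over all genes is given for this or later counts of that kind. Over all genes 1 member was called and, adjusted over the list alone, 20 were. Besides Ifi44, the members with the smallest p were Usp18 (0.97 ± 0.464 CPM in WT, 33.7 ± 6.38 in KO), Gbp3, a guanylate-binding protein gene (0.902 ± 0.267 and 12.6 ± 2.34), and Bst2, which encodes the virus-tethering protein tetherin (3.98 ± 2.36 and 61.4 ± 21.3). Their adjusted p values over all genes were 0.082, 0.1 and 0.1. The summed level of the list was 255 and 526 CPM in WT replicates 1 and 2, and 1830 and 1720 CPM in KO replicates 1 and 2. T and natural killer cell genes, summed, were at 63 and 44.8 CPM in WT and at 36.5 and 319 CPM in KO, so they were high in KO replicate 2 alone. Leaving out each library in turn gave adjusted p values from 1.04e-36 to 3.78e-21 for the interferon list.

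**Figure D1:**
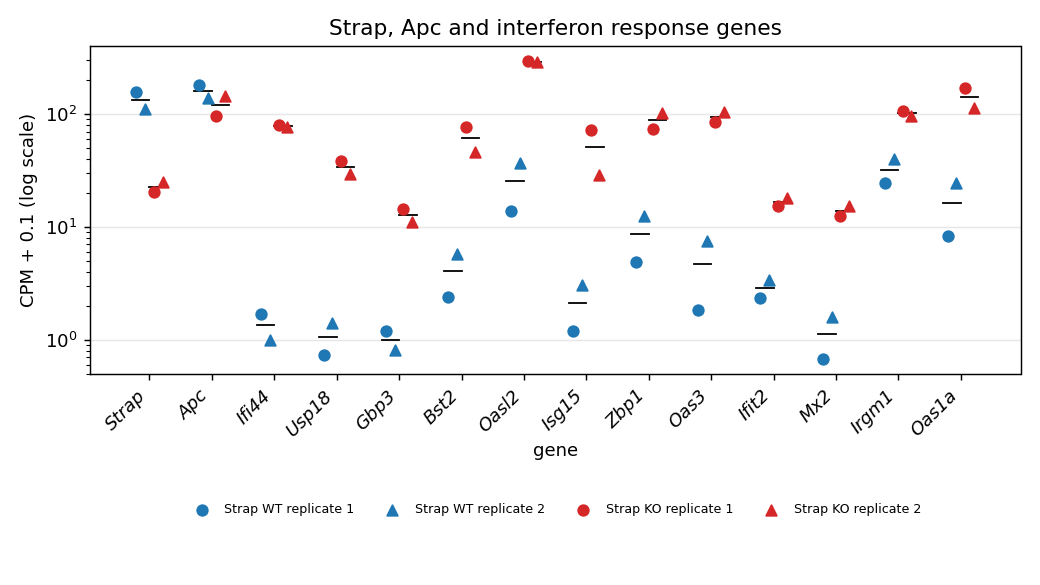
CPM plus 0.1 (TMM-scaled, log axis) of Strap, Apc and 12 interferon response genes in each library. Blue points are WT and red points KO, circles are replicate 1 and triangles replicate 2, and black lines are group means; Ifi44 is at 1.6 and 0.908 CPM in WT and at 80.7 and 76.9 CPM in KO.

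Wnt and beta-catenin target genes fell as a list in KO. Of 25 measured members, 20 were lower and 5 higher, with a median log2 fold change of -0.70 (mean -1.96, camera adjusted p = 5.38e-07, and adjusted p = 0.678 with an estimated correlation). In 14 members both KO libraries lay below both WT libraries. Over all genes 0 members were called and, adjusted over the list alone, 9 were, all lower. The first was Lgr5, the R-spondin receptor gene that marks crypt base stem cells, on chromosome 10 from 115450314 to 115587780. Lgr5 was at 34.5 and 70.6 CPM in WT and 4.85 and 6.27 CPM in KO, a log2 fold change of -3.24 (SE 0.41), so that 10.6% of the WT level was left. Its adjusted p was 0.1 over all genes, 0.00629 adjusted over the list alone and 5.4e-10 in DESeq2. Tnfrsf19, which encodes the receptor Troy, had a log2 fold change of -2.39, Rnf43, a ubiquitin ligase gene that limits Wnt receptors, -1.08, and Ephb3, an ephrin receptor gene of the crypt, -0.82.

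The other 5 of these 9 genes were also lower in each KO library than in both WT libraries. They were higher in WT replicate 1 than in WT replicate 2. So were Tnfrsf19 (19.8 and 10.3 CPM), Rnf43 (74.4 and 67.7) and Ephb3 (34.4 and 31.1). Nkd1, a feedback inhibitor of Wnt signalling, was at 97.7 and 6.42 CPM in WT and 1.37 and 0.545 CPM in KO. Prox1, a homeobox gene active in lymphatic endothelium and in Wnt-driven adenoma cells, was at 39.3 and 3.83 CPM in WT and 0.0683 and 0.341 CPM in KO. The secreted Wnt inhibitor gene Wif1 was at 34.5 and 0.973 CPM in WT and 0.0683 and 0.273 CPM in KO. Dkk3 was at 22.7 and 2.14 CPM in WT and 0.41 CPM in KO replicate 1, and was not listed in KO replicate 2. Apcdd1, which encodes a membrane inhibitor of Wnt signalling, was at 5.71 and 2.6 CPM in WT, was not listed in KO replicate 1 and was at 0.0681 CPM, a count of 1, in KO replicate 2. Other named target genes did not pass. Axin2, a feedback target of the pathway, had a log2 fold change of -0.43 (adjusted p = 0.489), Myc -0.04 (0.946), Cd44 0.09 (0.903) and Sox9 -0.48 (0.461). Ccnd1, the cyclin D1 gene, was at 103 and 221 CPM in WT and 366 and 286 CPM in KO (1.01, 0.305). The list kept an adjusted p between 4.26e-07 and 0.000715 when any 1 library was left out.

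Intestinal stem cell genes also fell as a list. Of 26 measured members 22 were lower, with a median log2 fold change of -0.44 (camera adjusted p = 0.000103, and adjusted p = 0.793 with an estimated correlation). Over all genes 0 were called and, adjusted over the list alone, 6 were, all lower: Lgr5, Tnfrsf19 and Rnf43, which also stand on the Wnt list, with Phlda1 (-1.61), Cd24a (-1.06) and Sorl1 (-0.79). In 10 members both KO libraries lay below both WT libraries. Ascl2, a transcription factor gene of crypt base stem cells, was at 11.2 ± 5.88 CPM in WT and 10.8 ± 2.38 CPM in KO (-0.04, adjusted p = 0.971). Olfm4, a secreted crypt protein gene, was at 189 and 876 CPM in WT and 176 and 348 CPM in KO (-1.02, adjusted p = 0.521). Without WT replicate 2 the stem cell list had an adjusted p of 0.148.

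**Figure D2:**
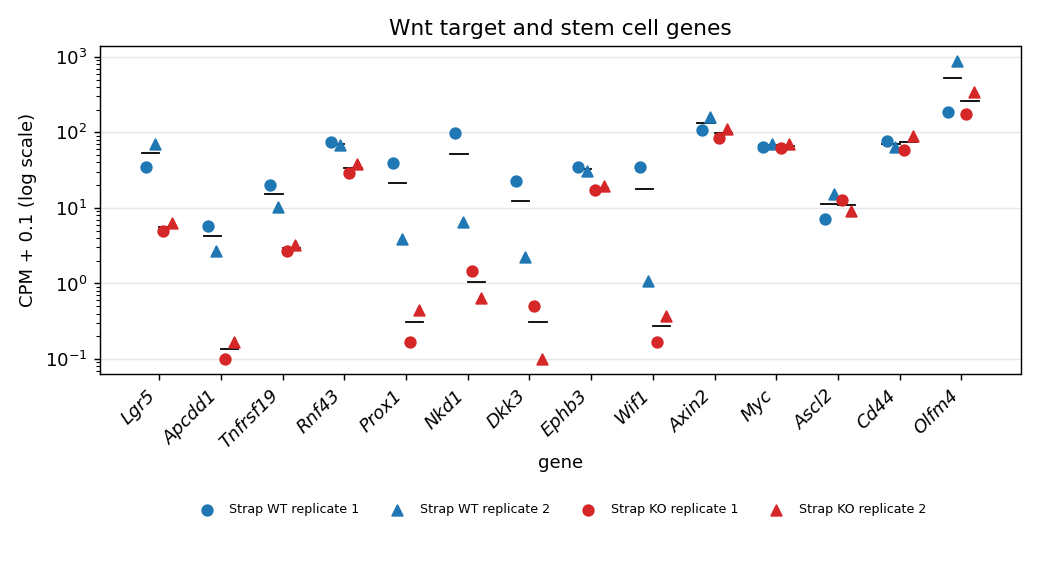
CPM plus 0.1 (TMM-scaled, log axis) of 14 Wnt target and stem cell genes in each library, with values not listed drawn at 0.1. Blue points are WT and red points KO, circles are replicate 1 and triangles replicate 2, and black lines are group means; Lgr5 is at 34.5 and 70.6 CPM in WT and at 4.85 and 6.27 CPM in KO.

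Among the pathways that Strap has been tied to, TGF-beta response genes fell as a list. Of 20 measured members 17 were lower, with a median log2 fold change of -0.52 (camera adjusted p = 0.00398, and adjusted p = 0.793 with an estimated correlation). No member was called over all genes or adjusted over the list alone. The members with the smallest p were Thbs1, the thrombospondin 1 gene (52.2 and 10.3 CPM in WT, 1.37 and 3.13 in KO), Fn1, the fibronectin gene (24.6 and 2.21 in WT, 0.342 and 0.204 in KO), Tgfbr1, a TGF-beta receptor gene (log2 fold change -0.97), and Cyr61 (21.4 and 3.24 in WT, 3.28 and 1.64 in KO). Thbs1, Fn1 and Cyr61 were highest in WT replicate 1, and without that library the list had an adjusted p of 0.266. Notch pathway genes did not pass: 9 of 24 were higher and 15 lower, with a median of -0.14 and a camera adjusted p of 0.279. Notch1 had a log2 fold change of -0.55 (adjusted p = 0.353), the Notch target gene Hes1 -0.03 (0.966) and the ligand gene Jag1 0.13 (0.861). The Notch members with the smallest p were Maml3 (-0.95), Lfng (-1.14) and Notch3 (-2.31), with adjusted p values of 0.27, 0.289 and 0.316. Genes of polycomb repressive complex 2, which methylates histone H3, had a median of -0.14 over 12 members while the set test pointed up (camera adjusted p = 0.902) and pointed down without KO replicate 1 (0.954). Its catalytic gene Ezh2 was at 47.7 ± 8.27 CPM in WT and 42 ± 4.41 CPM in KO (-0.18, adjusted p = 0.711). The 8 SMN complex genes other than Strap had a median of 0.16 (camera adjusted p = 0.527).

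Tuft cell genes fell as a list in KO. Of 12 measured members of this chemosensory lineage 11 were lower, with a median log2 fold change of -2.20 (camera adjusted p = 5.81e-06, and adjusted p = 0.793 with an estimated correlation). Over all genes 0 were called and, adjusted over the list alone, 2 were: Avil, the advillin gene (55.1 and 23 CPM in WT, 6.28 and 3.27 in KO), and Ptgs1, the cyclooxygenase 1 gene (3.02 and 5.65 in WT, 0.342 and 0.136 in KO). Trpm5, the taste-transduction channel gene, was at 7.31 and 33.4 CPM in WT and 5.74 and 1.98 CPM in KO, and Alox5ap, a leukotriene synthesis gene, at 2.57 and 9.02 CPM in WT and 1.64 and 0.681 CPM in KO, so both were highest in WT replicate 2. Without WT replicate 2 the tuft list had an adjusted p of 0.0558. Paneth cell genes, which encode antimicrobial proteins of the small-intestinal crypt, fell as a list too, with 17 of 18 members lower and a median of -0.64 (camera adjusted p = 0.0157, and adjusted p = 0.793 with an estimated correlation). Habp2 (-1.41) was the 1 member called adjusted over the list alone, and 0 were called over all genes. Lyz1, the Paneth lysozyme gene, was at 5710 and 14400 CPM in WT and 4610 and 4220 CPM in KO, and Pnliprp2 was at 59.3 and 215 CPM in WT and 38.9 and 28.5 CPM in KO. Reg3g, an antibacterial lectin gene, stood apart with 594 and 1730 CPM in WT and 3990 and 2570 CPM in KO. The Paneth list was highest in WT replicate 2, with a summed 46600 CPM against 15100 to 25900 CPM in the other 3 libraries. Without WT replicate 2 its adjusted p was 0.717 in the other direction, and without KO replicate 2 it was 0.549.

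The other epithelial lineages did not pass the set test. Goblet cell genes had a median log2 fold change of -0.31 over 19 members (camera adjusted p = 0.189), which became 6.01e-08 without WT replicate 1 and 0.0511 in the other direction without WT replicate 2. Absorptive cell genes had a median of -0.21 over 26 members (0.527). Enteroendocrine genes had a median of -0.40 and a mean of -0.11 over 20 members, while the set test pointed up (0.8) and pointed down without WT replicate 1 (0.176) and without KO replicate 2 (0.38). Regional genes showed small-intestinal transcripts in all 4 libraries. Apoa1, the apolipoprotein A1 gene, was at 2630 to 7930 CPM, the sucrase-isomaltase gene Sis at 1970 to 4710 CPM, the lactase gene Lct at 159 to 908 CPM and Gata4, a transcription factor gene of the proximal small intestine, at 27.3 to 165 CPM. Apoa4 and Fabp6, chosen like Apoa1, Sis and Gata4 after their values were seen, varied widely: Apoa4 from 143 CPM in WT replicate 2 to 4200 CPM in WT replicate 1, and Fabp6, the ileal bile acid-binding protein gene, from 118 CPM in KO replicate 2 to 2450 CPM in WT replicate 2. Genes of the colon chosen in the same way were low: Car1 at most 4.22 CPM, Aqp8 at most 0.834, Hoxb13 at most 0.779, Insl5 at most 0.26 and Hoxd13 at most 0.0649. Between the genotypes, the small intestine list had a median of 0.43 and a mean of 0.09 over 21 members (camera adjusted p = 0.156). Its members with the smallest p were Treh (log2 fold change 0.74), Slc10a2 (84.9 and 259 CPM in WT, 70.1 and 11.4 in KO), Reg3a (0.58) and Lct (1.23). This list had an adjusted p of 8.28e-09 without WT replicate 1, 0.0338 without KO replicate 1, and 0.72 in the other direction without WT replicate 2. The colon list had a median of -0.86 over 10 members (0.205, and 0.00289 without WT replicate 1). Its members with the smallest p were Sult1c2 (3.02 and 13.4 CPM in WT, 0.888 and 0.818 in KO), Muc6 (404 and 3.11 in WT, 0.137 and 1.02 in KO) and Lypd8 (log2 fold change 1.14).

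**Figure D3:**
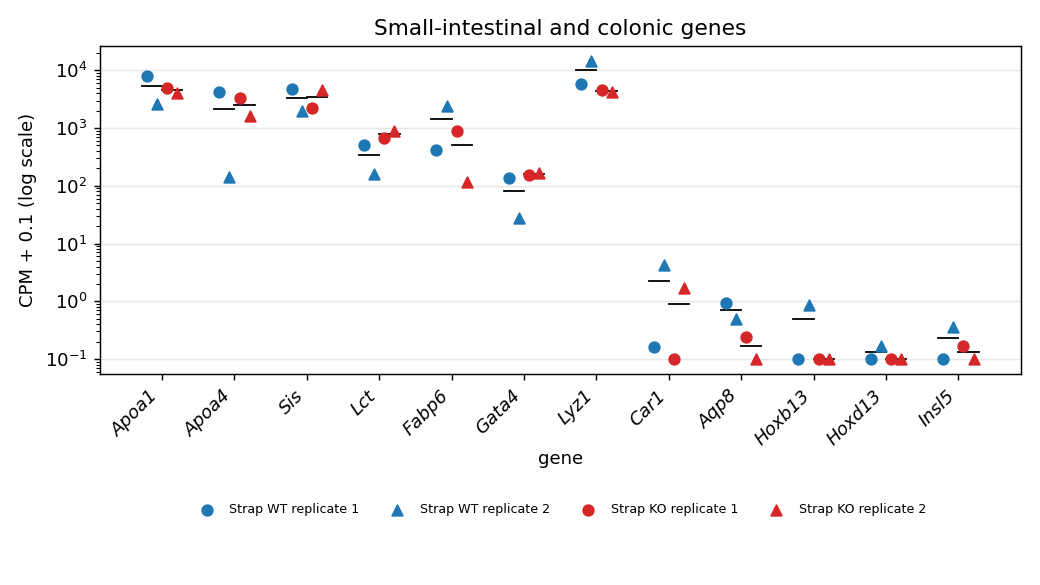
CPM plus 0.1 (TMM-scaled, log axis) of 7 small-intestinal and 5 colonic genes in each library, with values not listed drawn at 0.1. Blue points are WT and red points KO, circles are replicate 1 and triangles replicate 2, and black lines are group means; Apoa1 is at 2630 to 7930 CPM and Car1 at most at 4.22 CPM.

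Genes of growth rose as lists. MYC and ribosome biogenesis genes were higher in 23 of 25 members, with a median log2 fold change of 0.38 (camera adjusted p = 0.000183, and adjusted p = 0.793 with an estimated correlation), and both KO libraries lay above both WT libraries in 19. Odc1, the first enzyme gene of polyamine synthesis, had a log2 fold change of 0.98, the spermidine synthase gene Srm 1.12, Rrp9 1.12 and Rrs1 0.78. Cell cycle genes were higher in 25 of 35 members, with a median of 0.29 (camera adjusted p = 0.0278, and adjusted p = 0.793 with an estimated correlation). The cyclin gene Ccne1 had a log2 fold change of 0.78 and E2f2 0.52. The mitotic genes Cdc20 (19.9 and 57.6 CPM in WT, 86.2 and 54.9 in KO) and Ccna2 (62.2 and 155 in WT, 196 and 157 in KO) were lowest in WT replicate 1. No member of either list was called over all genes or adjusted over the list alone. Without WT replicate 1 the cell cycle list had an adjusted p of 0.823 in the other direction, and without KO replicate 1 it had 0.181, while the ribosome list stayed between 1.87e-05 and 0.00409.

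Immediate early stress genes fell as a list, with 17 of 20 members lower and a median log2 fold change of -1.18 (camera adjusted p = 0.00311, and adjusted p = 0.793 with an estimated correlation). Egr1, a growth factor-induced transcription factor gene, was at 387 CPM in WT replicate 1 and 16.7 CPM in WT replicate 2, against 12.8 and 13.2 CPM in KO. Dusp1, a MAP kinase phosphatase gene, was at 84.8 and 5 CPM in WT and 2.8 and 3.27 CPM in KO. Btg2 had a log2 fold change of -1.07 and Junb -1.1. No member was called over all genes or adjusted over the list alone, and the list had an adjusted p of 0.798 without WT replicate 1 and 0.194 without KO replicate 2. Regenerative and fetal-like epithelium genes did not pass, with a median of -2.02 over 16 members (camera adjusted p = 0.0793). Ly6a, an interferon-inducible surface antigen gene, was the 1 member called adjusted over the list alone, at 7.25 and 3.89 CPM in WT and 46.9 and 34.8 CPM in KO (log2 fold change 2.87). Clu, the clusterin gene, was at 1040 and 10.5 CPM in WT and 6.83 and 3.61 CPM in KO, Anxa1 at 50.8 and 3.11 CPM in WT and 1.09 and 0.136 CPM in KO, and Sprr1a at 22.2 and 1.88 CPM in WT and 0.41 and 0.613 CPM in KO. This list had an adjusted p of 0.798 in the other direction without WT replicate 1, 2.24e-08 without WT replicate 2 and 0.028 without KO replicate 1. Hypoxia and glycolysis genes had a median of -0.36 over 21 members (0.0793, 4.83e-07 without WT replicate 2, and 0.091 in the other direction without WT replicate 1), and p53 target genes -0.06 over 20 members (0.312).

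Of the other cell types, endothelial genes fell as a list, with 6 of 7 members lower and a median log2 fold change of -1.59 (camera adjusted p = 0.00783, and adjusted p = 0.793 with an estimated correlation). Over all genes 0 members were called and, adjusted over the list alone, 3 were: Prox1, Cdh5 and Sox17. Cdh5, the VE-cadherin gene, was at 35.6 and 0.649 CPM in WT, not listed in KO replicate 1 and at 0.0681 CPM in KO replicate 2. Sox17, a transcription factor gene of endoderm and arteries, was at 62 and 1.36 CPM in WT and not listed in either KO library, so no fold is given for it. Without Sox17 5 of 6 members were lower, with a median of -1.34. Vwf, the von Willebrand factor gene, was at 4.81 and 0.779 CPM in WT and 0.956 and 0.886 CPM in KO. The summed list was at 163 CPM in WT replicate 1 and at 17.1, 11.1 and 11.5 CPM in WT replicate 2 and KO replicates 1 and 2, and without WT replicate 1 its adjusted p was 0.251. Most of the level in WT replicate 1 came from Sox17, Prox1 and Cdh5, while Pecam1, Kdr, Tie1 and Emcn, endothelial genes chosen after their values were seen, were at most 1.29, 0.321, 0.615 and 0.0642 CPM in any library. T and natural killer cell genes were higher in 15 of 16 members, with a median of 1.28 (camera adjusted p = 0.0569). Gzma, a granzyme gene of cytotoxic lymphocytes, was at 26.4 and 15 CPM in WT and 15 and 152 CPM in KO, Gzmb at 7.38 and 5.26 CPM in WT and 6.01 and 50.9 CPM in KO, Klrd1 at 0.77 and 0.454 CPM in WT and 0.683 and 5.38 CPM in KO, and Nkg7 at 1.48 and 1.69 CPM in WT and 1.37 and 11.5 CPM in KO. Without KO replicate 1 this list had an adjusted p of 7.2e-16, and without KO replicate 2 it had 0.173 in the other direction.

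The remaining cell type lists did not pass. Macrophage and dendritic cell genes had a median log2 fold change of 0.33 over 12 members (camera adjusted p = 0.622, 0.0245 without KO replicate 1, and 0.18 in the other direction without KO replicate 2). Fibroblast genes had 0.40 over 5 members (0.622). Their set test pointed the other way without WT replicate 2 and without KO replicate 2, where 14 and 13 members passed the filter. Smooth muscle genes had a median of -0.41 over 6 members (0.396). B and plasma cell genes had a median of -0.01 and a mean of 0.08 over 5 members (0.8 with the test pointing up, 0.0165 without KO replicate 1, and 0.815 in the other direction without KO replicate 2). Neutrophil, mast cell, enteric neuron, adipocyte and pancreatic acinar genes had 2, 3, 4, 4 and 3 tested members, too few for a set test. With a library left out, genes high in 1 library can pass the filter, and some of these lists could be tested. Neutrophil genes (8 members) pointed lower without WT replicate 2, KO replicate 1 or KO replicate 2, settings that all keep WT replicate 1. Enteric neuron genes (5 to 9 members) pointed lower whichever library was left out. Mast cell genes (5 members) pointed lower without WT replicate 2 and higher without KO replicate 2. As the filter can choose members by 1 library, these directions are no test of the genotype. In these 5 lists 0 members were called over all genes and, adjusted over the list alone, Kit, Ret and Pnliprp1 were called lower. Kit, a receptor gene of mast cells and of some crypt cells, was at 30.3 and 47.3 CPM in WT and 8.06 and 11.5 CPM in KO. Ret was at 27 and 6.55 CPM in WT and 1.84 and 2.04 CPM in KO, and Pnliprp1 at 9.88 and 3.05 CPM in WT and 0.41 and 0.204 CPM in KO.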

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

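The crossed pairing of replicate numbers and the tests of the MHC lists were chosen only after the results were seen. The counts of genes higher and lower, 1 and 0 in edgeR, were the same with DESeq2 size factors, the stricter filter and the 2-fold minimum. They were 0 and 0 with library size alone and with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 19 and 6 with no filter, and 235 and 432 with DESeq2. They were 46 and 70 with the replicate number as a block, which also parts the libraries by their Xist and Y-linked pattern and let the regenerative (0.000919) and small intestine (0.0309) lists pass, although the labels do not pair the libraries and deviations of same-numbered libraries had a correlation of -0.123, and 65 and 99 with the crossed pairing. Leaving out a library gave 0 to 72 higher and 0 to 299 lower. Strap kept its direction in every setting and passed with no filter (-2.55), DESeq2 (-2.57) and the block (-2.55). Leaving out a library gave from -2.77, which passed, to -2.32. Ifi44 stayed at 4.29 or more in every setting and its call was lost with library size alone, both limma fits and without KO replicate 1 or KO replicate 2. Of the set tests 10 passed, 0 with an estimated correlation, 0 with fry and 9 to 15 with a library left out. With an estimated correlation and with fry the adjusted p values were 0.678 and 0.403 for interferon genes, 0.678 and 0.452 for Wnt targets, 0.793 and 0.452 for stem cell genes, and 0.793 and 0.497 for tuft cell genes. With a library left out they were 1.04e-36 to 3.78e-21 for interferon genes, 4.26e-07 to 0.000715 for Wnt targets, 6.01e-08 to 0.148 for stem cell genes and 2.29e-14 to 0.0558 for tuft cell genes. Genes that turned direction had log2 fold changes with a library left out of -0.52 to 0.65 (Ascl2), -1.76 to 0.49 (Olfm4), -0.15 to 0.07 (Myc), -0.27 to 0.38 (Cd44), -0.46 to 0.3 (Hes1), -0.07 to 0.38 (Jag1), -0.37 to 0.02 (Ezh2), -2.36 to 0.23 (Vwf), -0.07 to 3.02 (Gzmb), -0.46 to 2.89 (Gzma) and -0.21 to 2.87 (Nkg7). Ascl2 also turned with limma on log2(FPKM + 0.1) (0.01) and the block (0.04). Set tests that turned had adjusted p values with a library left out of 4.14e-08 to 0.823 (cell cycle), 3.05e-11 to 0.717 (Paneth), 7.2e-16 to 0.173 (T and natural killer), 2.24e-08 to 0.798 (regenerative), 8.28e-09 to 0.72 (small intestine), 6.01e-08 to 0.338 (goblet), 4.83e-07 to 0.215 (hypoxia), 0.0326 to 0.954 (fibroblast), 0.0245 to 0.948 (macrophage), 0.0165 to 0.815 (B and plasma cell genes), 0.0576 to 0.38 (enteroendocrine), 0.727 to 0.954 (polycomb) and 8.73e-05 to 0.51 (MHC class II genes). The enteroendocrine and polycomb lists also turned with limma on log2(FPKM + 1) (0.998 each). Leaving out a library changes which samples are compared and which genes pass the filter. For the other settings the cause was not tested. Over all alternatives, values of the named genes kept their direction and side of the threshold 907 times, passed in addition 121 times, lost a call 5 times and turned 17 times. The set tests of the 26 lists and of the MHC lists did so 183, 13, 30 and 18 times. With 2 libraries per group, 6 of 48 genes changed 2-fold were called in simulated data.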

Other observations

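The 7 tests behind the patterns below, and the MHC lists, were chosen only after the results were seen. MHC class I presentation genes, whose products cut, transport and display peptides on the cell surface, were higher in KO in all 10 measured members. Both KO libraries lay above both WT libraries in all 10, and the median log2 fold change was 1.91. If the 4 libraries were interchangeable, chance would give that order for 16.7% of single genes, and members that move together are not independent. As the list was chosen after the results were seen, neither this count nor its set test is independent support. The list had a camera adjusted p of 2.99e-18, from 2.31e-20 to 2.66e-09 with a library left out, and an adjusted p of 0.664 with an estimated correlation. Tap1, a peptide transporter gene, was at 43.6 ± 13.9 CPM in WT and 303 ± 105 CPM in KO, a log2 fold change of 2.8. The immunoproteasome genes Psmb9 and Psmb8 had log2 fold changes of 2.65 and 2.87, and H2-K1, a class I heavy chain gene, 1.64, with adjusted p values over all genes from 0.103 to 0.147.

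MHC class II genes, which serve antigen presenting cells and can be switched on in epithelium, did not follow the genotype. Their summed level was 781 and 2260 CPM in WT replicates 1 and 2, and 445 and 3370 CPM in KO replicates 1 and 2. The 7 members had a median log2 fold change of 0.41 and a camera adjusted p of 0.733, which was 8.73e-05 without KO replicate 1, and in the other direction 0.51 without WT replicate 1 and 0.0135 without KO replicate 2. Cd74, the invariant chain gene, was at 463 and 1250 CPM in WT and 247 and 1790 CPM in KO.

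Interferon response genes were higher in both KO libraries. T and natural killer cells as the whole cause would make them follow those cells, but between KO replicates 2 and 1 the interferon members differed by a median log2 of 0.05 (quartiles -0.39 and 0.42), against 2.98 (quartiles 2.49 and 3.35) for the T and natural killer members. The make-up of WT replicate 1 is not the whole cause either, since against WT replicate 2 alone the KO mean was higher by a median log2 of 2.53 (quartiles 1.35 and 3.37). The genotype itself and an infection or housing shared by the KO mice stay open and untested against each other, since the labels give no cage, litter or day.

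Wnt target genes were lower in KO. The make-up of 1 WT library alone as the whole cause would leave the list level against the other WT library. The list had a camera adjusted p of 2.5e-06 without WT replicate 1 and 4.26e-07 without WT replicate 2. With all libraries and an estimated correlation, its adjusted p was 0.678. Its median log2 was -0.64 (quartiles -2.11 and -0.04) against WT replicate 2 and -0.89 (quartiles -2.74 and -0.19) against WT replicate 1. These medians and quartiles argue against 1 WT library alone as the whole cause for this list, but do not exclude it. Each of these comparisons rests on 1 WT library. The p values without a library also rest on the preset correlation of 0.01, so they cannot decide. The WT libraries also differed from each other, with WT replicate 1 high in regenerative genes and WT replicate 2 high in Paneth genes. Small intestine members were higher in WT replicate 1 than in WT replicate 2 by a median log2 of 1.26. The ileal gene Fabp6, chosen after its values were seen, went the other way, at 422 CPM in WT replicate 1 and 2450 CPM in WT replicate 2. A different make-up in each WT library therefore cannot be excluded as the cause. Less adenoma tissue in both KO libraries cannot be told apart from the genotype. The regenerative genes differed from WT replicate 2 by a median log2 of -0.23 (quartiles -0.87 and 0.5), going both ways. From WT replicate 1 they differed by a median log2 of -2.84. WT replicate 1 itself lay above WT replicate 2 by a median log2 of 2.71, so the comparison with WT replicate 2 cannot decide. A lower share of stem cells as the whole cause of the lower Lgr5 counts cannot be excluded by the values. The other 25 stem cell members had a median log2 fold change of -0.43 (quartiles -0.79 and -0.08), and 0 lay at or below the value of Lgr5. Lgr5 was already known to have the smallest p of the list. The other members need not be confined to the cells that express Lgr5.

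Small-intestinal transcripts were abundant in libraries labelled colon adenoma. RNA mostly from small-intestinal mucosa is a candidate explanation, as 20 of 21 small intestine members reached 10 CPM in every library against 4 of 14 colon members. A minority of small-intestinal RNA in colon RNA would put most of the colon members on no other list at that level, but 1 of the 7 reached it. For these genes the values argue against such a minority. It is not excluded, since no library gives the level of these genes in colon alone. The other 7 colon members, and 0 small intestine members, also stand on another list. The labels place all 4 libraries in the same tissue, so the design gave no biological explanation to set against these.

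Of genes chosen after their values were seen, Col1a1, a collagen gene, was at most 1.6 CPM, Vim at most 12.3 CPM and Ptprc, the leukocyte gene for CD45, at most 21.9 CPM, while the epithelial gene Epcam was at 1540 to 2020 CPM. Other members of the fibroblast and T cell lists were higher, with Fbln1 at 53.6 to 91.1 CPM and Cd8a at 31.1 CPM in KO replicate 2. Notum, a secreted Wnt inhibitor gene chosen in the same way, was at 51 CPM in WT replicate 1 and at most 1.62 CPM elsewhere.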
